A study of Mus musculus with 27 samples.

How the data were processed

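Total RNA was sequenced from the mouse embryonic stem cell line E14 and from 2 knockout (KO) lines made on that background, 1 for Quaking (gene Qk) and 1 for Sam68 (gene Khdrbs1). Both genes encode STAR proteins, a family of RNA-binding proteins. Each line was sampled as stem cells (day 0) and as embryoid bodies, aggregates in which the cells differentiate, at days 3 and 10. The labels give 3 biological replicates for each of the 9 groups, 27 libraries in all. RNA was depleted of ribosomal RNA, libraries were made with a stranded total RNA kit, and reads were paired, 125 bases each. Each knockout is represented by 1 line, so a difference between clones cannot be separated from the effect of the knockout. The numbers given to the Sam68-labelled libraries do not overlap those of the other lines, so a library batch and the Sam68 label cannot be told apart.

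The deposited files hold raw read counts per gene, 1 file per library, with 51826 gene identifiers and no normalisation by the authors. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.5.3a and the mouse genome build GRCm38 (mm10). The program that counted reads, its strand setting and the annotation release are not given in the sources used here. Every value was checked to be a whole number, and 53.5% of the nonzero values were odd, so the deposited counts are not sums in which every pair adds 2. Whether single mates were counted is not known. Identifiers were matched without their version to the GENCODE mouse annotation, release 21 on GRCm38, which held 51633 of them (99.6%). With the version, 91.9% matched. Symbols, biotypes and coordinates come from that annotation.

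The totals ran from 56.5 to 77.3 M counts per library. The intervals and floors that follow from such totals cover counting error only, since reads without molecular identifiers are not independent molecules. Between replicates the logged CPM correlated across genes at Pearson r = 0.992 to 0.9956, a description of the libraries, since genes are not independent replicates. Averaged over genes, the variance between replicates exceeded counting error by a factor between 3.37 and 204.97, a mean in which abundant genes weigh most. At these depths a kept gene had a median of 292 counts per library. For such a gene, counting error was larger than the common biological coefficient of variation of the fits at day 0 (3.6%) and day 3 (5.5%), and smaller than that at day 10 (10.6%).

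Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), counts were scaled by TMM, and groups were compared with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR 4.0.16, limma 3.58.1, R 4.3.3). A gene was called at an adjusted p under 0.05. Each day was fitted alone with its 9 libraries, which share 1 estimate of the spread. The wild-type libraries of the 3 days were fitted together, and each interaction of line and day was fitted on 12 libraries. Log2 fold changes (log2FC) are given with their standard errors (SE), and expression as CPM, as mean ± SD over 3 libraries. No pseudocount was added to the printed CPM. Where a gene had no count in a group, a floor of 3 counts over the group's libraries gives a lower bound on the fold. Where a group held 1 to 3 counts, the CPM stands alone. The p-values measure only the spread between these samples.

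A set of 33 gene lists for cell states, lineages, pathways and technical classes was fixed before the data were examined, together with the tests, their alternatives and the rule for the genes named. The lists were tested with limma's camera with a preset correlation between genes of 0.01, which compares a list with all other genes, and with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with a correlation estimated from the data is given beside it. Fry was run too: its P value tests whether the genes of a list move 1 way on balance and its Mixed P value whether they change in either direction, and neither compares the list with other genes. Lists with fewer than 4 measured members have counts only. Counts of members are given over all genes tested and adjusted over the list alone.

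The genes named are the STAR family; the 6 largest rises and 6 largest falls of each comparison among called genes with a mean of at least 1 CPM and no overlap between the libraries compared; up to 2 rising and 2 falling members with the smallest p from the 8 lists with the smallest camera p; the 4 largest interactions per direction; and the 5 largest shared changes per direction. Predicted models and pseudogenes were left out, and genes listed without a symbol are not reported here. The text leaves out some of these genes for length, and genes named beyond the rule are said to be chosen after their values were seen.

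Reads can match several genes. The share of each gene's 50-base windows that occur in other genes, on either strand, was computed from the annotated transcript sequences. It also counts genes that overlap at 1 place and misses copies that are not annotated. The share of exon bases that overlap other genes was computed from the annotation. Named genes above about 5% on either are marked as uncertain. Every comparison was also fitted on only the 14391 protein-coding genes below 5% on both, an alternative chosen after seeing the data. Other alternatives were DESeq2 size factors in the same fit, no filter, DESeq2's Wald test (DESeq2 1.42.0), all 27 libraries in 1 fit, only the 6 libraries compared, the replicate number as a block, and leaving out each library in turn.

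Replicate numbers recur in every group. In wild type and Quaking KO the library numbers also run in blocks by replicate, each block holding both lines and all days. Whether the replicate numbers pair the samples was checked at each day with the correlation, across genes, of the deviations of same-numbered libraries from their group means. Only for wild type and Quaking KO at day 3 did all 3 exceed 0.1 (r = 0.60, 0.24 and 0.18), so the fits with the number as a block stand beside that result.

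The pipeline was tested on simulated data with 3 libraries per group and the spread of each comparison. Each run changed 66 or 67 genes at each size, far fewer than were called in any real comparison. The shares below describe that setting and not the real fits. For Quaking KO against wild type at day 0, 61.2% of genes with a true log2 change of 0.5 were called, 76.1% with 1 and 97% with 2, and 5.5% of the calls were genes simulated as unchanged. At day 3 the same shares were 53.7%, 86.6% and 95.5%, with 7.6% unchanged, and at day 10 they were 44.8%, 71.6% and 97%, with 9.6% unchanged. Every library entered the comparisons, and splicing was not analysed here, because counts per gene do not show it.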

Results

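Gene expression was measured in 3 mouse lines followed through embryoid body differentiation: wild-type E14 embryonic stem cells, a Quaking KO line and a line labelled Sam68 KO. The series asks what STAR proteins, which bind RNA, do in early mammalian development. Each line was sampled at days 0, 3 and 10 with 3 biological replicates, which gives 9 groups and 27 libraries. The wild-type libraries held 67 to 67.9 M (1e+06) counts at day 0, 66.5 to 69.2 at day 3 and 66.4 to 71.3 at day 10. The Quaking KO libraries held 63.3 to 66.4 M at day 0, 68.8 to 71.4 at day 3 and 64.4 to 71.6 at day 10. The Sam68-labelled libraries held 56.5 to 62.1 M at day 0, 59.4 to 63.4 at day 3 and 73.5 to 77.3 at day 10. Over the 2000 most variable genes, the first principal component held 68.1% of the variance, the second 14.9% and the third 13.8%. Values below are log2FC ± SE with adjusted p from edgeR, and CPM as mean ± SD, n = 3 per group. Coordinates are on GRCm38.

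The Qk transcript, which encodes Quaking, was lower in the Quaking KO line at every day but was not lost. It stood at 159 ± 9.22 CPM against 235 ± 3.81 in wild type at day 0 (log2FC −0.58 ± 0.04, adjusted p = 1.85e-09), at 118 ± 6.26 against 227 ± 7.41 at day 3 (−0.95 ± 0.05, 2.79e-09). At day 10 it stood at 204 ± 6.24 against 267 ± 14.9 at day 10 (−0.41 ± 0.06, 0.00232). Khdrbs1 (ENSMUSG00000028790), which encodes Sam68, was not lost in the Sam68-labelled libraries. Its level there was 91.4 ± 4.48 CPM against 98.8 ± 1.37 in wild type at day 0 (log2FC −0.03 ± 0.04, adjusted p = 0.576) and 101 ± 1.67 against 115 ± 26.9 at day 10 (−0.25 ± 0.13, 0.132). The day 0 CPM lie further apart than that log2FC, because the fit of the day is scaled on its own. At day 3 it fell by 0.70 ± 0.06 on the log2 scale, from 160 ± 7.43 in wild type to 96.6 ± 7.21 (adjusted p = 1.15e-07). The wild-type mean at day 10 rests on replicate 1 (146 CPM against 98.1 and 100). For Khdrbs1, Sam68 KO against wild type, day 10, the log2FC was −0.03 without wild type day 10 replicate 1 (adjusted p = 0.573), and −0.35 and called without wild type day 10 replicate 2 (0.0446). A count per gene cannot show a small deletion in an exon, so neither level tells how much protein was made. Qk lies on chromosome 17 from 10202601 to 10319854, and Khdrbs1 on chromosome 4 from 129703164 to 129742303.

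The STAR genes also moved in the other line. Khdrbs1 fell by 0.43 ± 0.04 in Quaking KO cells at day 0 (73.9 ± 4.15 CPM, adjusted p = 7.42e-08), and did not pass at day 3 (0.07 ± 0.06, adjusted p = 0.582) or day 10 (−0.13 ± 0.13, adjusted p = 0.585). Qk fell in the Sam68-labelled line by 0.10 ± 0.04 at day 0 (adjusted p = 0.0368) and by 0.30 ± 0.04 at day 3 (adjusted p = 1.81e-05), with a day 10 level of 273 ± 8.16 CPM (adjusted p = 0.755). For Qk, Sam68 KO against wild type, day 0, the call was lost without wild type day 0 replicate 1 (adjusted p = 0.0973), Sam68 KO day 0 replicate 1 (0.0754) or Sam68 KO day 0 replicate 2 (0.187). Khdrbs3, which encodes the related protein SLM2, fell in the Sam68-labelled line at all 3 days, by 0.56 ± 0.04, 0.30 ± 0.05 and 0.55 ± 0.08, and rose by 0.36 ± 0.08 in Quaking KO cells at day 10 (adjusted p = 0.0188). For Khdrbs3, Quaking KO against wild type, day 10, that call was lost without wild type day 10 replicate 2 (adjusted p = 0.0542), Quaking KO day 10 replicate 2 (0.0695) or Quaking KO day 10 replicate 3 (0.0593). In wild-type cells Khdrbs1 rose by day 3 (0.72 ± 0.11, adjusted p = 9.36e-05). Qk did not pass there (−0.03 ± 0.06, adjusted p = 0.711) and rose by day 10 (0.22 ± 0.06, adjusted p = 0.00424). For Qk, wild type, day 10 against day 0, the value on protein-coding genes without shared sequence was 0.04 (adjusted p = 0.468).

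**Figure D1:**
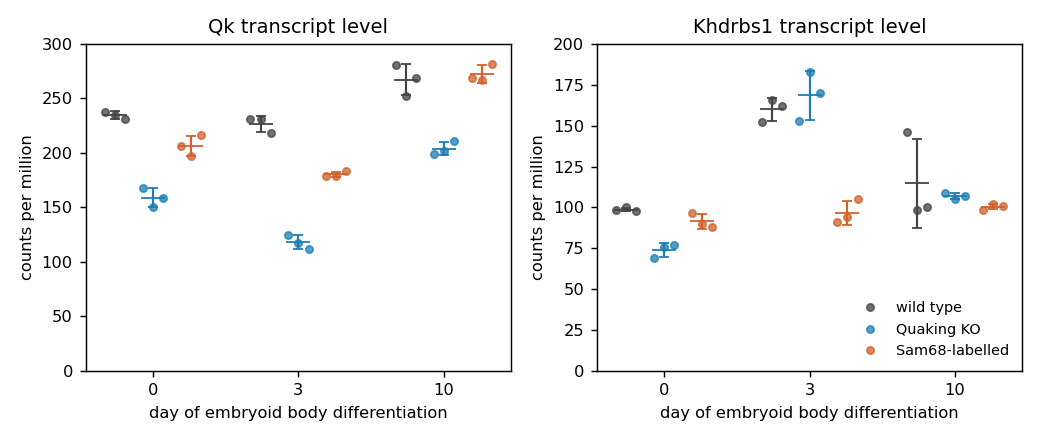
CPM of Qk and Khdrbs1 in each library (points) by day of differentiation and line, with bars at the mean ± SD of 3 libraries. Qk is lowest in Quaking KO cells at every day, and Khdrbs1 falls below wild type in the Sam68-labelled line at day 3, 96.6 against 160.

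Wild-type cells left the naive state by day 3. Klf4, a reprogramming factor, fell from 137 ± 6.48 to 3.73 ± 0.268 CPM (log2FC −5.18 ± 0.08). Nr0b1, a nuclear receptor of naive cells, fell from 100 ± 7.77 to 5.23 ± 0.19. The gastrulation gene T (Brachyury, chromosome 17 from 8434423 to 8442496) rose from 0.465 ± 0.228 to 270 ± 63.1 CPM. The streak gene Eomes rose from 3.14 ± 0.114 to 294 ± 43.2 CPM (6.57 ± 0.13, adjusted p = 3.34e-13). Fgf5, a marker of primed epiblast, rose 470-fold to 104 ± 9.97 CPM, and Fgf8, a streak growth factor, 398-fold to 73.4 ± 6.77. All 16 naive pluripotency genes measured fell (camera adjusted p = 7.43e-09; adjusted p = 0.205 with an estimated correlation). Of 13 formative and primed genes 12 rose and 1 did not pass (12 rose and 1 fell when adjusted over the list alone; adjusted p = 5.27e-07, or 0.205 with an estimated correlation). The transcription factors Zic2 (4.83 ± 0.09) and Sall2 (3.57 ± 0.08) led them. Of 14 primitive streak genes 11 rose, 1 fell and 2 did not pass, with Wnt3 at 42.7 ± 4.51 CPM from 1.0 ± 0.167 and Mesp2 the one that fell (adjusted p = 6.25e-05; 0.387 with an estimated correlation). All 17 cholesterol synthesis genes rose, among them Sqle (1.89 ± 0.06) (adjusted p = 8.01e-09; 0.183 with an estimated correlation). Of 14 Wnt targets 10 rose and 1 fell, with the feedback gene Axin2 at 126 ± 10.2 CPM from 15.3 ± 0.619 (adjusted p = 0.000216; 0.387 with an estimated correlation). The endoderm factor Foxa2 rose 21.6-fold, and 9 of 12 definitive endoderm genes rose with 2 falling (adjusted p = 0.00674; 0.387 with an estimated correlation). Of 14 amino acid and ER stress genes 11 fell and 1 rose, with Trib3 at 6.18 ± 0.449 CPM from 58.3 ± 4.17 and Chac1 at 2.5 ± 0.145 from 31.7 ± 2.08 (adjusted p = 0.000525; 0.427 with an estimated correlation). All 12 two-cell-like genes measured fell (adjusted p = 8.57e-06; 0.387 with an estimated correlation), but members such as Zscan4c hold 85.5% of their sequence in other genes and are uncertain.

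By day 10 the wild-type embryoid bodies held transcripts of heart, blood, yolk sac endoderm and connective tissue. Col1a1, the main collagen of connective tissue, rose from 1.17 ± 0.0395 to 873 ± 132 CPM (log2FC 9.57 ± 0.14). Apob, a lipoprotein of endoderm and liver, rose from 2.95 ± 0.143 to 1450 ± 296 (8.97 ± 0.17), and the embryonic globin gene Hbb-y from 0.0709 ± 0.025 to 193 ± 21.9 (11.41 ± 0.17). The macrophage genes Adgre1 and C1qb had no count at day 0 and reached 39.9 ± 6.11 and 39 ± 8.17 CPM, at least 2440-fold and 2380-fold higher with a floor of 3 counts over the group. The platelet factor Pf4 was at least 2630-fold higher and the apelin receptor Aplnr at least 1890-fold. All 25 cardiac muscle genes rose (camera adjusted p = 3.50e-09; 0.0757 with an estimated correlation). Among them were the myosins Myh6 (3.1 ± 0.224 to 364 ± 10.6 CPM) and Myh7 (0.66 ± 0.0623 to 281 ± 33.3), uncertain because about 20% of their sequence is shared. Of 36 Hox genes, which pattern the body axis, 34 rose and 2 fell (adjusted p = 1.08e-07; 0.0757 with an estimated correlation). Of 25 extraembryonic endoderm genes 24 rose and Rhox5 fell (adjusted p = 9.16e-08; 0.0757 with an estimated correlation). For Rhox5, wild type, day 10 against day 0, the call (−0.25 ± 0.11, adjusted p = 0.0463) was lost without any 1 of the day 0 libraries, or of day 10 replicates 1 and 3 (adjusted p = 0.0743 to 0.139). Of 18 blood genes 17 rose and 1 did not pass (adjusted p = 1.87e-06; 0.0875 with an estimated correlation), and of 18 matrix and fibroblast genes 17 rose and Thy1 fell (adjusted p = 5.76e-07; 0.0795 with an estimated correlation). All 14 core pluripotency genes fell (adjusted p = 3.58e-07; 0.0757 with an estimated correlation), with Dnmt3l, a DNA methylation cofactor, at 1.61 ± 0.283 CPM from 386 ± 9.46. So did 15 of 16 naive genes (adjusted p = 7.44e-07; 0.124 with an estimated correlation), with Esrrb at 4.29 ± 0.764 CPM from 504 ± 15.4. Of 19 cell cycle genes 18 fell, with the S-phase cyclin Ccne1 at 27.4 ± 2.59 CPM from 287 ± 14.1 (adjusted p = 1.87e-06; 0.303 with an estimated correlation). At day 3 against day 0, 12830 of 21060 genes were called, 6487 higher, and at day 10 against day 0 17017, 8723 higher. Among protein-coding genes without shared sequence 8193 and 9949 of 11402 were called.

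Quaking KO stem cells at day 0 held more of several naive pluripotency transcripts and less of epithelial, primed and imprinted ones. Tbx3, a naive-state transcription factor, rose from 53.8 ± 1.86 to 104 ± 2.31 CPM (log2FC 0.93 ± 0.04, adjusted p = 3.86e-13), and Tfcp2l1 from 421 ± 2.92 to 664 ± 26.4 (0.64 ± 0.03). Esrp1, an epithelial splicing regulator, fell from 9.6 ± 0.374 to 2.65 ± 0.158 CPM (−1.87 ± 0.08), and the keratin Krt18 from 25.5 ± 2.05 to 12.2 ± 0.389. Peg10, a paternally expressed imprinted gene, fell from 645 ± 34 to 325 ± 13.1 CPM (adjusted p = 5.27e-13). The de novo DNA methyltransferase Dnmt3a fell by 0.52 ± 0.03 and Dnmt3b by 0.56 ± 0.03, the latter uncertain because 9.8% of its sequence is shared.

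Of the 16 naive genes 14 rose, 1 fell and 1 did not pass (camera adjusted p = 2.40e-05; 0.0686 with an estimated correlation). The one that fell was Dppa3 (−2.61 ± 0.15), a maternal factor whose sequence is shared by 16.5%. Of 13 formative and primed genes 10 fell and 3 did not pass (adjusted p = 4.91e-05), of 14 epithelial genes 11 fell and 3 did not pass (2.40e-05), and of 22 imprinted genes 17 fell and 5 did not pass, or 19 fell when adjusted over the list alone (3.16e-06). These 3 lists held with an estimated correlation, each at adjusted p = 0.033. So did the 4 Y-linked genes tested, all lower (adjusted p = 1.17e-05; 0.033 with an estimated correlation). The RNA helicase gene Ddx3y (chromosome Y from 1260771 to 1286629) stood at 28.3 ± 1.27 against 139 ± 2.65 CPM (−2.31 ± 0.04) and Uty at 14.8 ± 0.712 against 60.5 ± 1.68. Eif2s3y fell by 1.31 ± 0.04 and Kdm5d stood at 0.0118 ± 0.0102 against 0.371 ± 0.0657 CPM. Of 18 extraembryonic endoderm genes 11 fell and 2 rose (adjusted p = 0.000228; 0.0905 with an estimated correlation). The endoderm factor Gata4 stood at 8.26 ± 0.383 against 14.7 ± 0.0455 CPM and Rhox5 at 9.68 ± 0.193 against 50.2 ± 0.85. Of 7 trophoblast genes 6 fell (adjusted p = 0.00934; 0.0905 with an estimated correlation), including Tfap2c (−0.86 ± 0.06). Of 12 two-cell-like genes 11 fell (adjusted p = 0.00126; 0.313 with an estimated correlation), all of them in families with shared sequence. The neural crest list had a median log2FC of −0.12 while its camera direction was up (adjusted p = 0.937).

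The largest rises of single genes at day 0 were C1qtnf9 (0.801 ± 0.0785 to 4.8 ± 0.595 CPM, 2.56 ± 0.13), the phospholipase gene Pla2g4e (1.65 ± 0.13), the cadherin Cdh13 (1.52 ± 0.20) and the keratin Krt17 (14.4 ± 1.89 to 41.6 ± 2.08 CPM). The largest falls included the X-linked genes Fmr1nb (11.2 ± 0.491 to 1.22 ± 0.0857 CPM, −3.22 ± 0.10), Xlr3a (−3.61 ± 0.22, 44.8% shared) and Fndc3c1 (−3.36 ± 0.14, 12.7% shared). They also included the interferon-induced GTPase gene Gbp2 (−3.05 ± 0.18), the Y-linked Usp9y (−3.02 ± 0.11) and Vrtn (−2.99 ± 0.21). In all, 7881 of 19841 genes tested were called, 3856 higher and 4025 lower, of which 917 changed at least 2-fold, 198 up and 719 down. Among protein-coding genes without shared sequence 5652 of 10312 were called.

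At day 3 the Quaking KO embryoid bodies fell short of wild type in extraembryonic endoderm transcripts. Col4a1, a basement membrane collagen, stood at 117 ± 8.74 against 258 ± 6.29 CPM (log2FC −1.14 ± 0.06, adjusted p = 9.47e-09), and Rhox5 at 3.7 ± 0.423 against 17.3 ± 1.15 (−2.23 ± 0.09). Of the 22 genes of this list 16 fell and 6 did not pass, or 19 fell when adjusted over the list alone (camera adjusted p = 1.09e-22; 0.0809 with an estimated correlation). Stxbp5, which encodes the vesicle fusion regulator tomosyn, rose from 27.8 ± 0.771 to 66.6 ± 3.88 CPM (1.26 ± 0.05, adjusted p = 2.79e-10), and the synaptic fusion protein gene Stx1a from 6.54 ± 0.669 to 18.5 ± 0.444, 2.82-fold.

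Of 17 cholesterol synthesis genes 5 rose and 12 did not pass, or 7 rose when adjusted over the list alone (adjusted p = 0.000299; 0.0809 with an estimated correlation). Mvd rose by 0.27 ± 0.04 and Lss by 0.26 ± 0.04. Of 22 imprinted genes 5 fell, or 6 when adjusted over the list alone (adjusted p = 0.00314; 0.082 with an estimated correlation). Among them were Nnat (11.3 ± 1.04 to 3.95 ± 0.293 CPM) and the zinc finger gene Plagl1 (2.23 ± 0.074 to 0.458 ± 0.0746). Of 15 naive genes 4 rose and Klf4 fell, or 8 rose and 1 fell when adjusted over the list alone (adjusted p = 0.0135; 0.379 with an estimated correlation). Klf2 rose from 8.32 ± 0.788 to 12.3 ± 1.25 CPM. Of 12 definitive endoderm genes 3 fell and 1 rose (adjusted p = 0.0135; 0.379 with an estimated correlation). The trypsin inhibitor Spink1 fell by 0.99 ± 0.12 and Sox17, 15% shared, by 1.57 ± 0.14. The N-cadherin gene Cdh2 fell by 0.73 ± 0.12. Further large rises were Phf21b (9.3 ± 1.37 to 23 ± 3.31 CPM) and the noncoding Mir670hg (1.38 ± 0.17). Further large falls were Fmr1nb (5.93 ± 0.422 to 0.351 ± 0.0166 CPM, −4.07 ± 0.18), the zinc finger gene Zfp951 (−2.72 ± 0.23), Pnma5 (−3.04 ± 0.27, 25.9% shared) and the Y-linked Usp9y (−3.10 ± 0.15), Ddx3y (−2.80 ± 0.04) and Uty (−2.36 ± 0.06). The streak gene T stood at 181 ± 63.9 CPM against 270 ± 63.1 and was not called, but it was lower in all 3 pairs of replicates, and with the replicate number as a block on the 9 libraries it was (log2FC −0.62, adjusted p = 0.00242). With that block 10 of 14 streak genes were called, all lower, against 1 without it (camera adjusted p = 0.0781 without it). These 10 were lower in all 3 pairs, Nodal and Fgf8 were higher in all 3, and the set was looked at after its values were seen. In all, 1381 of 19711 genes were called, 607 higher and 774 lower, of which 151 changed at least 2-fold, 19 up and 132 down. Among protein-coding genes without shared sequence 1267 of 10450 were called. For Quaking KO against wild type, day 3, replicate number as a block on the 9 libraries gave 1891 calls and the 6 compared gave 2433, while without wild type day 3 replicate 2 there were 749 and without wild type day 3 replicate 3 there were 801. Replicate 1 stood apart in both lines at this day, with the mitochondrial ribosomal RNA mt-Rnr2 at 9.53% of counts in wild type and 10.96% in Quaking KO against group means of 7.3% and 7.41%. This was not particular to day 3. Replicate 1 also had the highest mt-Rnr2 share of both groups at day 0 (13.73% and 14.77%) and at day 10 (9.34% and 9.81%).

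At day 10 the Quaking KO embryoid bodies held less heart muscle and hypoxia-response RNA than wild type, and some neural and trophoblast genes were higher. Actn2, which encodes a sarcomere actinin (chromosome 13 from 12269426 to 12340760), fell from 23 ± 3.87 to 3.97 ± 1.06 CPM (log2FC −2.55 ± 0.18, adjusted p = 2.80e-05), and Myh6, whose sequence is shared by 20.2%, from 364 ± 10.6 to 86.4 ± 33.4. Of 25 cardiac muscle genes 15 fell and 10 did not pass, or 20 fell when adjusted over the list alone (camera adjusted p = 2.99e-10; 0.519 with an estimated correlation). All 15 hypoxia and glycolysis genes fell (adjusted p = 7.88e-11; 0.519 with an estimated correlation). The peptide hormone gene Adm stood at 1.81 ± 0.531 against 5.91 ± 0.871 CPM and the kinase gene Pdk1 at 107 ± 10.7 against 170 ± 10. The forebrain factor Lhx2 rose from 8.1 ± 0.463 to 17.8 ± 1.02 CPM (1.11 ± 0.10, adjusted p = 0.000148).

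Of 14 neural progenitor genes 6 rose and 8 did not pass, or 8 rose when adjusted over the list alone (adjusted p = 0.000338; 0.519 with an estimated correlation). Zic1, a factor of the dorsal neural tube, stood at 16.8 ± 3.69 against 7.51 ± 0.91 CPM. Of 17 neuronal genes 4 rose, or 6 when adjusted over the list alone (adjusted p = 0.00071; 0.519 with an estimated correlation). The growth cone gene Gap43 stood at 15.9 ± 2.67 against 7.62 ± 0.787 CPM. The mean log2 CPM of the progenitor list was 1.91, 2.36 and 2.76 in Quaking KO replicates 1, 2 and 3 against 1.78, 1.85 and 1.75 in wild type, and that of the neuronal list 1.27, 1.51 and 1.99 against 1.15, 1.02 and 0.91. Replicate 1 thus lay close to wild type on both. Of 10 trophoblast genes 4 rose and 6 did not pass (adjusted p = 0.0419; 0.519 with an estimated correlation), with list means of 0.87, 0.88 and 0.78 against −0.05, 0.22 and −0.05. Of 25 extraembryonic endoderm genes 12 fell and 13 did not pass, or 17 fell and 1 rose when adjusted over the list alone (adjusted p = 3.17e-07; 0.519 with an estimated correlation). The hepatocyte factor Hnf4a stood at 21.2 ± 2.08 against 36.9 ± 3.72 CPM, and the endocytic adaptor gene Dab2 fell by 0.75 ± 0.10. Of 36 Hox genes 15 fell, 3 rose and 18 did not pass, or 20 fell when adjusted over the list alone (adjusted p = 2.51e-06; 0.519 with an estimated correlation). The posterior gene Hoxa13 stood at 1.93 ± 0.449 against 6.99 ± 1.13 CPM. The anterior Hoxb2 and Hoxb3 rose, but 25.9% and 51.4% of their sequence is shared. Of 13 formative and primed genes 3 rose, or 6 when adjusted over the list alone (adjusted p = 0.000839; 0.519 with an estimated correlation), with Zic2 at 0.71 ± 0.13. The Y-linked genes were all lower again (adjusted p = 3.68e-07; 0.425 with an estimated correlation), Ddx3y by 2.56 ± 0.15, Uty by 2.23 ± 0.11 and Eif2s3y by 1.51 ± 0.08.

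The largest single rises at day 10 were the cathepsin gene Ctsj (0.195 ± 0.128 to 2.96 ± 0.888 CPM, log2FC 3.88 ± 0.81, adjusted p = 0.011), the GABA receptor gene Gabrp (3.77 ± 0.40), and Stmn4, a stathmin of neurons (3.42 ± 0.39). Serpinb9e (28.4% shared), Rhox6 (16.6%) and Kng1 (17.2%) also rose and are uncertain. Large falls were Plagl1 (289 ± 38.7 to 49.7 ± 12.4 CPM, −2.57 ± 0.18), Vstm2a (−2.77 ± 0.29), and the Y-linked Usp9y (−3.23 ± 0.25). The imprinted noncoding H19 (247 ± 76.2 to 32.9 ± 6.38 CPM) overlaps another gene by 9.2% and Magohb shares 26.8%, so both are uncertain. In all, 2392 of 20503 genes were called, 1016 higher and 1376 lower, of which 581 changed at least 2-fold. Among protein-coding genes without shared sequence 1952 of 11217 were called. Without Quaking KO day 10 replicate 2 there were 1399, the cardiac genes that fell numbered 9 and the Hox genes that rose 0. Without wild type day 10 replicate 2 the extraembryonic genes that fell numbered 7, the neural progenitor genes that rose 3, the trophoblast genes that rose 2 and the formative genes that rose 1. Quaking KO day 10 replicate 2 also held 3.94% of its counts in the ribosomal RNA gene model Gm42418 and 0.7% in Lars2, which averaged 27.4 ± 8.46 CPM in wild type. For Quaking KO against wild type, day 10, a fit of all 27 libraries called 4863 genes.

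The Sam68-labelled libraries differed from the others in which kinds of RNA they held. At day 0 the nuclear Malat1 took 0.347% of counts against 0.126% in wild type, at day 3 0.337% against 0.125%, and at day 10 0.276% against 0.162%. Rn7sk, a small nuclear RNA that restrains transcription elongation, took 0.391%, 0.402% and 1.07% against 1.13%, 1.19% and 1.78%. Gene models still awaiting experimental support, with sense-intronic ones, took 0.287% and 0.271% at days 0 and 3 against 0.0802% and 0.0702%, and 0.0817% against 0.0851% at day 10. Genes whose sequence is shared with other annotated genes tended to be lower in these libraries. Of genes with the highest share of such sequence, 19.3% were at least 8-fold lower than wild type at day 0, 19.3% at day 3 and 17.3% at day 10, while among genes with none it was 0.3%, 0.4% and 1%. In Quaking KO cells 0.3%, 0.1% and 0.1% of the same class were. The replication-dependent histone genes Hist1h4m (8.48 ± 1.15 to 0.0905 ± 0.0462 CPM at day 0) and Hist1h2br (4.88 ± 0.659 to 0.0535 ± 0.00755), the mitochondrial mt-Nd3 (4.33 ± 0.387 to 0.0425 ± 0.017) and the signal recognition particle RNA Rn7s2 (117 ± 18.8 to 0.183 ± 0.016) all share 88.7% or more of their sequence with other annotated genes and are uncertain. The mitochondrial messages had a median log2FC of 0.04 and a mean of −2.90 at day 0, 0.67 and −1.95 at day 3, and −0.18 and −2.53 at day 10, with camera down each time (adjusted p = 0.15, 0.545 and 0.0869). Counts of called genes are therefore given beside those for protein-coding genes without shared sequence.

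**Figure D2:**
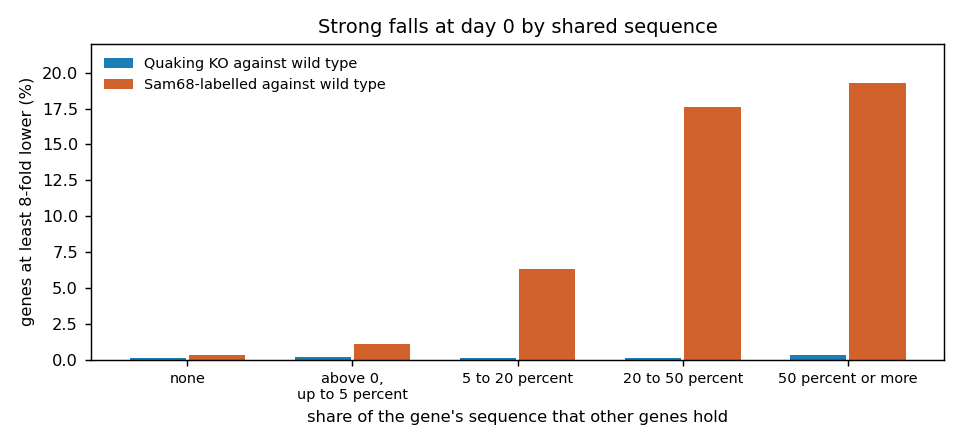
Percent of tested genes at least 8-fold lower than wild type at day 0, for Quaking KO and Sam68-labelled cells (bars), by the share of each gene's sequence that other genes hold. The bar reaches 19.3% for the Sam68-labelled line in the highest class and 0.3% for Quaking KO.

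At day 0 the Sam68-labelled stem cells held more extraembryonic endoderm RNA and less of some pluripotency and stress-response RNA. Gata4, a regulator of primitive endoderm (chromosome 14 from 63198922 to 63271692), rose from 14.7 ± 0.0455 to 68.8 ± 2.12 CPM (log2FC 2.32 ± 0.04, adjusted p = 2.22e-18), and Cubn, an endocytic receptor of visceral endoderm, from 38.5 ± 3.11 to 217 ± 3.25 (2.58 ± 0.05). Nanog, a core pluripotency factor, fell from 435 ± 13.9 to 228 ± 1.63 CPM (−0.85 ± 0.03, adjusted p = 1.69e-14), and Gdf3 from 111 ± 3.35 to 61.1 ± 1.04. Asns, which makes asparagine, fell from 565 ± 34.5 to 307 ± 4.76 CPM, and the stress-induced Trib3 from 58.3 ± 4.17 to 28.1 ± 0.122.

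Of 18 extraembryonic endoderm genes 13 rose, 3 fell and 2 did not pass (camera adjusted p = 0.00034; 0.343 with an estimated correlation), with Rbp4 (−1.34 ± 0.27) and Apob (−0.40 ± 0.10) among those that fell. Of 14 amino acid and ER stress genes 12 fell, Atf3 rose and 1 did not pass (adjusted p = 0.00164; 0.343 with an estimated correlation). Of 19 cell cycle genes 16 fell, Mki67 rose (0.29 ± 0.03) and 2 did not pass, with the helicase gene Mcm2 at −0.41 ± 0.03 (adjusted p = 0.0277; 0.639 with an estimated correlation). All 12 two-cell-like genes fell (adjusted p = 0.000298; 0.343 with an estimated correlation), each with shared sequence, so that result is uncertain. Of 14 core pluripotency genes 10 fell and 3 rose (adjusted p = 0.0739), and of 11 smooth muscle genes 8 fell and 2 rose (0.0739), with the myosin light chain Myl9 at 0.428 ± 0.0462 against 4.45 ± 0.275 CPM. Cholesterol synthesis genes had a median of −0.01 and a mean of 0.05. The largest rises were the kinase gene Ptk6 (0.393 ± 0.0855 to 3.38 ± 0.368 CPM, 3.19 ± 0.16), the BMP regulator Bmper (2.73 ± 0.0439 to 17.2 ± 0.894, 2.74 ± 0.07), the water channel Aqp8 (2.63 ± 0.17), the odorant receptor gene Olfr983 (2.75 ± 0.18) and Arhgap6 (3.15 ± 0.15, 11% shared). In all, 14757 genes were called, 7241 higher and 7516 lower, and 7293 of 10312 among protein-coding genes without shared sequence.

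At day 3 the Sam68-labelled embryoid bodies held less primitive streak RNA than wild type. T stood at 8.72 ± 4.2 CPM against 270 ± 63.1 in wild type, the streak homeobox gene Evx1 at 2.62 ± 0.895 against 37 ± 7.82 (log2FC −3.79 ± 0.22, adjusted p = 9.34e-10), and Wnt3, the ligand that starts the streak, at 9.32 ± 1.19 against 42.7 ± 4.51 (−2.17 ± 0.11). Eomes fell less, to 71.7 ± 15.5 against 294 ± 43.2 CPM, and still rose in this line from 3.2 ± 0.212 at day 0. The Wnt-induced factor Sp5 fell from 42.5 ± 10.9 to 2.35 ± 0.612 CPM (−4.14 ± 0.25) and Axin2 from 126 ± 10.2 to 49.4 ± 6.59 (−1.32 ± 0.08). Sox1, an early neural factor, stood at 6.51 ± 1.24 against 0.963 ± 0.248 CPM (2.79 ± 0.19, adjusted p = 4.49e-09).

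Of 14 streak and nascent mesoderm genes 12 fell and 2 rose (camera adjusted p = 0.00807; 0.684 with an estimated correlation). The risen ones were Mesp2 (0.79 ± 0.25) and Tbx6 (0.59 ± 0.22), both under 1 CPM. For Mesp2, Sam68 KO against wild type, day 3, the call was lost without wild type day 3 replicate 1 (adjusted p = 0.0548) or Sam68 KO day 3 replicate 3 (0.0578). For Tbx6, Sam68 KO against wild type, day 3, it was lost without wild type day 3 replicate 2 (0.0686), wild type day 3 replicate 3 (0.13) or Sam68 KO day 3 replicate 2 (0.155). Of 14 Wnt targets 13 fell and 1 did not pass (adjusted p = 0.00176; 0.569 with an estimated correlation). On genes without shared sequence the streak counts were also 12 and 2, with a median of −2.47, and 9 of 10 Wnt targets fell. Of 12 neural progenitor genes 9 rose and 1 fell (adjusted p = 0.052; 0.543 with an estimated correlation). The ciliary factor Rfx4 stood at 1.21 ± 0.0913 against 0.315 ± 0.0367 CPM. Of 22 extraembryonic endoderm genes 14 rose and the transthyretin gene Ttr fell (adjusted p = 0.0228; 0.684 with an estimated correlation). The laminin gene Lama1 stood at 409 ± 31.1 against 109 ± 1.34 CPM and Cubn at 729 ± 43.2 against 200 ± 10.4. The BMP-induced Id1 (−1.67 ± 0.13) and Id3 (−1.45 ± 0.10) fell, while Skil, an inhibitor of TGF-beta signalling, rose (0.37 ± 0.04). The cholesterol enzymes Cyp51 (−0.45 ± 0.04) and Msmo1 (−0.47 ± 0.04) fell. Of 13 structured noncoding RNAs 10 fell and the Y RNA gene Rny3 rose (adjusted p = 0.00807; 0.543 with an estimated correlation), which includes multi-copy families that are uncertain. The imprinted antisense Kcnq1ot1 rose from 53.6 ± 9.76 to 374 ± 13.6 CPM (2.83 ± 0.14), together with the rise in Malat1 and intronic models given above. Other large rises were Miat (3.20 ± 0.18) and Adam4 (3.32 ± 0.21), with 24.2% and 17.4% shared. Skeletal muscle genes had a median of 0.60 and a mean of −0.22. In all, 14411 genes were called, 7089 higher and 7322 lower, and 7124 of 10450 among protein-coding genes without shared sequence.

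**Figure D3:**
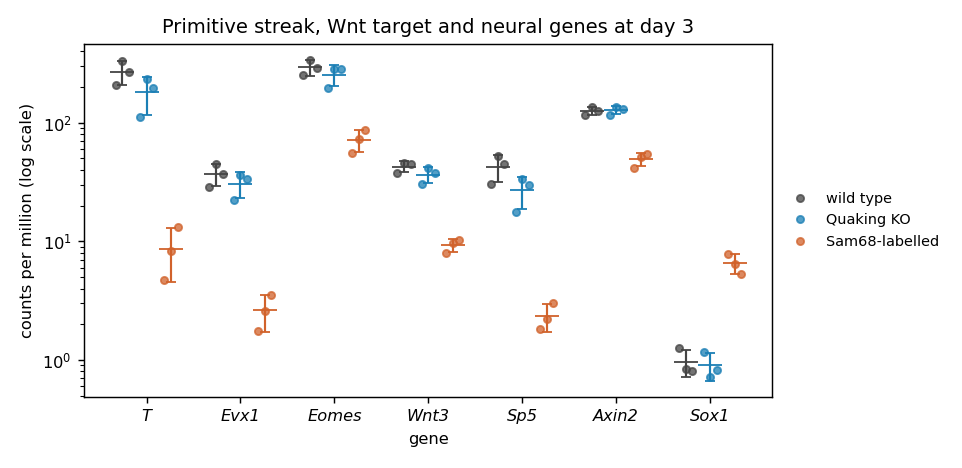
CPM (log scale) at day 3 of 7 genes in each library (points) of the 3 lines, with bars at the mean ± SD of 3 libraries. The streak genes T, Evx1, Eomes and Wnt3 and the Wnt targets Sp5 and Axin2 sit lower in the Sam68-labelled line, with T at 8.72 against 270, while Sox1 sits higher.

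At day 10 the Sam68-labelled embryoid bodies held more heart muscle and endoderm RNA and less Hox, blood and matrix RNA than wild type. Tnnt2, the cardiac troponin T gene, rose from 81.5 ± 15.5 to 284 ± 11.6 CPM (log2FC 1.75 ± 0.18, adjusted p = 1.25e-05), Actn2 from 23 ± 3.87 to 63.4 ± 5.54 and Gata4 from 155 ± 7.32 to 443 ± 23.5 (1.46 ± 0.07). Hoxa13 (chromosome 6 from 52257694 to 52260880) fell from 6.99 ± 1.13 to 0.538 ± 0.147 CPM (−3.75 ± 0.22, adjusted p = 3.62e-07). The embryonic globin Hbb-bh1 fell from 147 ± 13.7 to 56.5 ± 3.37 CPM (−1.43 ± 0.12), and the matrix collagens Col6a1 from 175 ± 34 to 61.1 ± 6.62 and Col6a2 from 89 ± 16 to 24.8 ± 2.99.

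Of 36 Hox genes 34 fell, Hoxc13 rose (1.32 ± 0.26) and 1 did not pass (camera adjusted p = 3.84e-10). Of 18 blood genes 16 fell and 2 did not pass, or 17 fell when adjusted over the list alone (8.77e-06), and of 18 matrix and fibroblast genes 17 fell (4.98e-05). Of 25 extraembryonic endoderm genes 19 rose and 3 fell (5.31e-05). Hnf4a stood at 112 ± 4.46 against 36.9 ± 3.72 CPM, and the fetal albumin relative Afp was among those that fell (−0.86 ± 0.21). Of 25 cardiac genes 19 rose and 3 fell, or 21 and 3 when adjusted over the list alone (0.000569). The early heart factors Isl1 (−1.01 ± 0.11) and Hand1 (−0.62 ± 0.08) fell. Of 14 Wnt targets 11 fell and Cdx2 rose (0.012), with the antagonist Dkk1 at −0.87 ± 0.08. Each of these 6 lists had adjusted p = 0.585 with an estimated correlation. On genes without shared sequence, 20 of 22 Hox genes fell and 16 of 20 cardiac genes rose. Of 16 epithelial genes 9 rose and 4 fell (adjusted p = 0.0183; 0.585 with an estimated correlation). The tight junction claudin Cldn7 stood at 69.2 ± 5.62 against 23.1 ± 2.64 CPM and Grhl3 at −0.86 ± 0.12. The skeletal actin Acta1 rose from 3.03 ± 0.61 to 22.5 ± 5.05 CPM (2.84 ± 0.22), and the natriuretic peptide Nppb from 0.644 ± 0.0167 to 3.85 ± 0.887 (2.52 ± 0.20). The potassium channel Kcnk16 rose from 1.69 ± 0.174 to 9.1 ± 0.0884, with Psca (2.47 ± 0.27) and Spns3 (2.41 ± 0.18). Nppa (2.52 ± 0.34) shares 53.4% of its sequence and is uncertain. Core pluripotency genes had a median of −0.58 and a mean of −0.22 with camera up (adjusted p = 0.995), and structured noncoding RNAs a median of 0.14 and a mean of −1.08. In all, 10377 genes were called, 4678 higher and 5699 lower, and 6124 of 11217 among protein-coding genes without shared sequence.

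**Figure D4:**
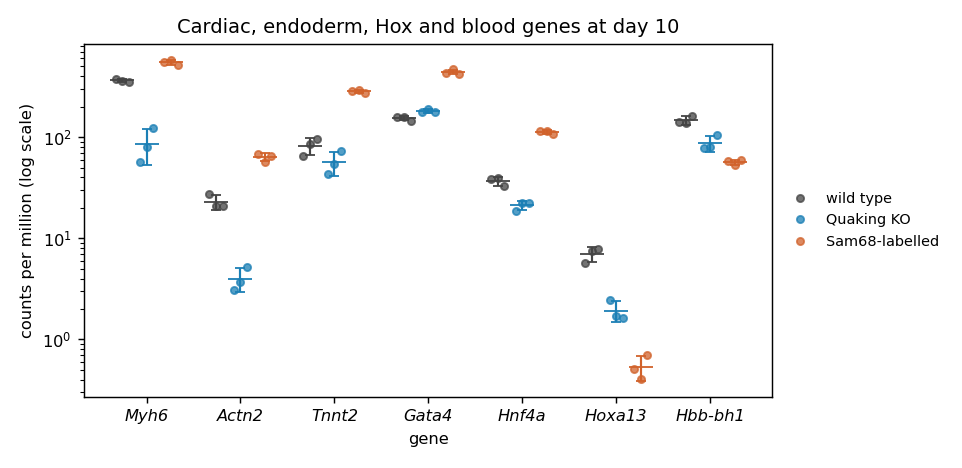
CPM (log scale) at day 10 of 7 genes in each library (points) of the 3 lines, with bars at the mean ± SD of 3 libraries. Actn2 falls from 23 in wild type to 3.97 in Quaking KO and rises to 63.4 in the Sam68-labelled line, while Hoxa13 is lower in both.

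Whether the change from day 0 differed between a knockout and wild type was tested with the interaction of line and day. In Quaking KO cells the ubiquitin ligase gene Trim67 rose more by day 3, from 0.0473 ± 0.041 to 38.2 ± 2.04 CPM against 0.507 ± 0.0347 to 29.1 ± 0.872 in wild type (interaction 3.79 ± 0.37, adjusted p = 1.52e-06). The leukotriene receptor gene Cysltr1 had a positive interaction too (3.21 ± 0.33) but stayed below wild type. It went from 0.0872 ± 0.00394 to 5.22 ± 0.921 CPM, against 1.11 ± 0.0105 to 7.1 ± 0.69 in wild type. For both genes the value can reflect the low level in Quaking KO at day 0. Usp26 fell more, from 1.33 ± 0.162 to 0.134 ± 0.0195 CPM (−2.37 ± 0.25). Of 14 epithelial genes 8 had a positive interaction and 6 did not pass, or 9 when adjusted over the list alone (camera adjusted p = 5.97e-06; 0.0376 with an estimated correlation). By day 10, Quaking KO interactions were positive in 11 of 13 formative and primed genes (1.56e-06; 0.0413 with an estimated correlation), 7 of 11 trophoblast genes (2.69e-06; 0.0387 with an estimated correlation) and 5 of 16 epithelial genes, or 8 when adjusted over the list alone (2.91e-05; 0.0387 with an estimated correlation). Cardiac interactions were negative in 10 of 25 cardiac genes with 1 positive, or 12 and 2 when adjusted over the list alone (8.15e-07; 0.239 with an estimated correlation). Hypoxia interactions were negative in 10 of 15 genes, or 12 when adjusted over the list alone (1.61e-06; 0.305 with an estimated correlation). Over all comparisons, 8 camera calls held with an estimated correlation: the 4 Quaking KO lists so named at day 0 and the 4 Quaking KO interaction lists with such a p above. The interactions use the same day 0 libraries, so they are not separate support. The epithelial, formative and trophoblast lists were mostly lower in Quaking KO at day 0, and a positive interaction can reflect that lower start. Esrp1, chosen after its values were seen, went from 2.65 ± 0.158 to 90.6 ± 3.04 CPM by day 3, against 9.6 ± 0.374 to 84.7 ± 1.79 in wild type. At day 10 some formative and trophoblast genes were also above wild type. Vstm2a rose in wild type from 0.529 ± 0.0363 to 4.02 ± 1.13 CPM and stood at 0.598 ± 0.26 in Quaking KO (−3.25 ± 0.41). Lars2 had the largest positive value, which rests on Quaking KO day 10 replicate 2 alone: its group mean was 2250 ± 3860 CPM. In all, 3172 genes were called at day 3 and 2978 at day 10, or 2687 and 2427 among protein-coding genes without shared sequence.

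In the Sam68-labelled line, T rose only to 8.72 ± 4.2 CPM by day 3 from 0.482 ± 0.0142 (interaction −5.04 ± 0.94, adjusted p = 0.000275), and Evx1 to 2.62 ± 0.895 from 0.522 ± 0.07 (−4.84 ± 0.52). Gad1, which makes the transmitter GABA, fell from 3.24 ± 0.137 to 0.222 ± 0.0897 CPM while wild type held 1.89 ± 0.261 and 2.99 ± 0.345 (−4.55 ± 0.24). Sox1 fell less than in wild type, from 8.2 ± 0.232 to 6.51 ± 1.24 against 18.2 ± 0.661 to 0.963 ± 0.248 CPM (3.87 ± 0.17, adjusted p = 1.88e-12). Pcnx2 (3.17 ± 0.21) and the neuronal migration gene Astn1 (3.28 ± 0.42) rose more. Interactions were negative in 11 of 14 Wnt targets (camera adjusted p = 5.93e-07; 0.214 with an estimated correlation) and in 10 of 14 streak genes with 1 positive (0.000178; 0.402 with an estimated correlation). By day 10 they were positive in all 14 amino acid and ER stress genes (3.11e-05; 0.292 with an estimated correlation) and in 14 of 25 cardiac genes with 1 negative, or 14 and 2 when adjusted over the list alone (0.000322; 0.244 with an estimated correlation). They were negative in 11 of 36 Hox genes with 2 positive, or 10 and 1 when adjusted over the list alone (5.13e-06; 0.292 with an estimated correlation). The smooth muscle actin Acta2 rose from 0.478 ± 0.0896 to 384 ± 53.8 CPM, against 4.51 ± 0.667 to 149 ± 29.3 in wild type (4.50 ± 0.28). The cation channel gene Trpm5 rose in wild type from 0.262 ± 0.068 to 3.8 ± 0.216 CPM and stood at 0.233 ± 0.0361 in the Sam68-labelled line (−4.63 ± 0.33). Cox6a2, a muscle form of a respiratory chain subunit, had no count at day 0 in this line and 11.6 ± 0.362 CPM at day 10, against 6.7 ± 0.948 in wild type. In all, 7111 genes were called at day 3 and 10271 at day 10, or 5104 and 5653 among protein-coding genes without shared sequence. The shift in kinds of RNA in these libraries was not equal over the days. Unsupported and sense-intronic models took 0.287% against 0.0802% in wild type at day 0, and 0.0817% against 0.0851% at day 10. Such a shift does not cancel in the day 10 interaction, and its share in these calls was not tested. Compared directly, the Sam68-labelled and Quaking KO lines differed in 15056 genes at day 0, 14206 at day 3 and 11609 at day 10, or 7544, 7070 and 6876 among protein-coding genes without shared sequence.

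Some genes moved the same way in both lines. H19 (9.2% overlap), Fmr1nb, Zfp951, the RNA export factor gene Nxf3 and Xlr3a (44.8% shared) were lower in both at day 0. Fmr1nb stood at 1.22 ± 0.0857 CPM in Quaking KO and 0.854 ± 0.174 in the Sam68-labelled line against 11.2 ± 0.491 in wild type. The hair cell cadherin Cdh23, the brush border myosin Myo1a, the protease gene Klk11 and Pla2g4e were higher in both, by up to 1.65. At day 3 the head organiser gene Lhx1 (1.12 ± 0.678 and 1.02 ± 0.478 against 5.21 ± 3.15 CPM) and Aplnr (0.874 ± 0.294 and 0.609 ± 0.263 against 3.33 ± 1.35) were lower in both, and Stxbp5 and the kinase gene Brsk2 higher. At day 10 Plagl1 (49.7 ± 12.4 and 45 ± 7.76 against 289 ± 38.7 CPM), Vstm2a and the mesothelial factor Tcf21 (1.54 ± 0.101 and 1.03 ± 0.174 against 8.46 ± 1.11) were lower in both. The neuropeptide precursor Pnoc (21.2 ± 4.31 and 23.5 ± 4.3 against 6.79 ± 1.71) and Tmem179 were higher in both. In all, 3629 genes were called in the same direction at day 0 (1631 higher and 1998 lower, where independent calls would give 1407.3 and 1524.7) and 2321 in opposite directions. At day 3 there were 683 (288 and 395 against 218.3 and 287.5 from independent calls) and 387 opposite, and at day 10 683 (283 and 400 against 231.8 and 382.5) and 920 opposite. At day 10 more genes thus moved in opposite directions than in the same one. The number from independent calls was not computed for opposite directions, so an excess in the same direction alone does not show that the lines moved alike. Among protein-coding genes without shared sequence, 974 were higher and 1396 lower in both at day 0 (773.1 and 1094.5 from independent calls, 1539 opposite), and 189 and 293 at day 3 (120.3 and 215.5, 274 opposite). At day 10 the 192 higher in both were fewer than the 210.1 from independent calls, the 295 lower in both were more than 259.4, and 703 were opposite. Both lines share their 3 controls, which also raises such a count. The 5 simulations of unchanged groups cannot show by how much. They were drawn around the mean of these controls and leave out the effects, so hardly any gene would be called. They gave 0 at each day, from which nothing is drawn. A fit of all 27 libraries gave 2371 for the genes called in both knockouts in the same direction, day 0 and 1503 for the genes called in both knockouts in the same direction, day 10. Without wild type day 3 replicate 2 the day 3 count was 325, without wild type day 3 replicate 3 it was 349, and without Quaking KO day 10 replicate 2 the day 10 count was 409.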

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

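The tests of the 3 patterns weighed here were chosen after the results were seen, while the splits of the libraries were planned.

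The change from day 0 differed between Quaking KO and wild type in 3172 genes at day 3 and 2978 at day 10, and between the Sam68-labelled line and wild type in 7111 and 10271, each by the interaction of line and day. The last of these can hold the shift in kinds of RNA between days given above. The Sam68-labelled and Quaking KO lines differed from each other in 15056 genes at day 0, 14206 at day 3 and 11609 at day 10.

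Genes that share much of their sequence with other annotated genes tended to have low counts in the Sam68-labelled libraries at all 3 days. Library depth as the cause is argued against, since the lowest total of the Sam68-labelled libraries at day 10 was 73.5 M counts, above every wild-type total, and these genes were still low there. A candidate explanation is that reads matching several genes were assigned differently in these files: 19.3% of the genes with the most shared sequence were at least 8-fold lower than wild type at day 0, a share that grew with the shared sequence. In the Quaking KO line the share was 0.3%. An effect of the Sam68 knockout itself cannot be told apart from this, because all libraries of that batch carry the same label.

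Primitive streak genes were lower than wild type in the Sam68-labelled line at day 3. Reads shared between genes do not account for it, since the list's median log2FC was −2.47 when only genes without shared sequence were fitted. A batch difference equal at every day is excluded as the whole cause by the median interaction of −2.65. Slower progress along the wild-type path was tested only as a delay in leaving the naive state. Such a delay would leave naive pluripotency genes higher and formative genes lower. Of 15 naive genes 3 were higher and 8 lower (median −0.39), and formative genes went both ways (median 0.01). Set against each line's own day 0, the interactions were negative in 8 of 16 naive genes with 3 positive. They were positive in 9 of 13 formative genes with 2 negative. These values argue against that delay, while a later one, between the formative state and the streak, was not tested. A hypothesis left open is that the line, through the knockout or through its clonal history, may form less streak or form it later. A batch difference that acts at day 3 alone was not tested.

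Y-linked genes were low in the Quaking KO line at all 3 days. Reads shared with X-linked copies are argued against, since no more than 2.49% of the sequence of any Y-linked gene tested is held by another gene. Loss of the Y chromosome from a share of the cells would, acting alone, lower all of them alike. Eif2s3y and Ddx3y differed in log2FC at day 0 by 1, from −1.31 ± 0.04 to −2.31 ± 0.04, so such loss is argued against as the whole cause. In the Sam68-labelled line at day 0 these genes also moved apart, to 0.77 ± 0.04 and −0.76 ± 0.04. Single Y-linked genes can thus vary between lines, and loss together with such variation is not excluded. An effect of the knockout and a difference between clones may each be involved, and 1 line per knockout cannot part them.

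For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split gave the most calls in 1 of 10 splits each time, with 7881, 1381 and 2392 for Quaking KO against wild type, 14757, 14411 and 10377 for Sam68 KO against wild type, 12830 and 17017 for wild type over time, and 15056, 14206 and 11609 between the knockouts, and the highest other split gave 0 in all 11. For the interactions of Quaking KO, 4 of the 100 drawn splits, the real one included, gave as many at day 3 (real 3172, highest other 3847). At day 10 it was 1, the real one itself (2978 and 1485). For those of Sam68 KO, again with the real one included, 4 gave as many at day 3 (7111 and 8568) and 2 at day 10 (10271 and 13071). The splits that mixed the lines at both days gave 0 each time, and the large ones point to a structure: those with 3847, 8568 and 1485 kept the groups of 1 day and mixed those of the other, and the one with 13071 kept both groups of each day with the labels exchanged at 1 day. Such splits carry the difference between the lines at the day kept, which fixes these counts, so they do not test the interactions and nothing about chance is drawn from them.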

How the results depend on the processing

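The fits on only protein-coding genes without shared sequence and with a replicate block on only the 6 libraries compared were chosen after seeing the data.

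Most named gene results kept their direction and their side of the threshold. Most of these genes were picked for a large change or a small p in the same data. Their stability was partly fixed by that choice and says little about the other genes called. Of the named gene results, 381 of 384 did so with DESeq2 size factors, 382 of 384 with no filter, 376 of 382 with DESeq2's Wald test, 366 of 384 with all 27 libraries in one fit, 348 of 352 with only the 6 libraries compared, 381 of 384 with the replicate block, 267 of 271 on only protein-coding genes without shared sequence, and 2389 of 2496 over the fits without each library in turn. Depth (a median of 292 counts per kept gene and library), 3 replicates and 1 line per knockout each limit these results, and they were not ranked. The replicate block alone moved no count of genes called in a comparison, or in both knockouts, by over 1.5 times, but it raised the streak genes called lower in Quaking KO at day 3 from 1 to 10 of 14. It was checked further for Quaking KO against wild type, day 3, where replicate 1 correlated best with its own number (r = 0.60 against −0.29), as did replicate 2 (0.24 against 0.20), and replicate 3 did not (0.18 against 0.39).

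On only protein-coding genes without shared sequence fewer genes are tested, and the counts were 7293 for Sam68 KO against wild type, day 0, 7124 for Sam68 KO against wild type, day 3, 6124 for Sam68 KO against wild type, day 10, 8193 for wild type, day 3 against day 0, 9949 for wild type, day 10 against day 0, and 5653 for Sam68 KO by time interaction, day 10 against day 0. They were 7544, 7070 and 6876 for Sam68 KO against Quaking KO, day 0, Sam68 KO against Quaking KO, day 3 and Sam68 KO against Quaking KO, day 10. For Quaking KO against wild type, day 3, the replicate block gave 1891 calls, and the replicate block on only the 6 libraries compared, which changes 2 choices at once, gave 2433, so that move cannot be put down to the block. With all 27 libraries in one fit, Quaking KO against wild type, day 10 gave 4863, and the genes called in both knockouts in the same direction, day 0 numbered 2371 and the genes called in both knockouts in the same direction, day 10 numbered 1503, where the cause was not tested. Of the gene lists, 169 were called by camera over 486 tests, 8 with an estimated correlation and 344 by fry, which tests something else.

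With fewer samples, leaving out 1 library gave 749 (without wild type day 3 replicate 2) to 1641 (without wild type day 3 replicate 1) for Quaking KO against wild type, day 3, and 1399 (without Quaking KO day 10 replicate 2) to 3139 (without wild type day 10 replicate 1) for Quaking KO against wild type, day 10. The genes called in both knockouts in the same direction, day 3 ran from 325 (without wild type day 3 replicate 2) to 1010 (without wild type day 3 replicate 1), and the genes called in both knockouts in the same direction, day 10 from 409 (without Quaking KO day 10 replicate 2) to 996 (without wild type day 10 replicate 1).

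Values that reversed were all uncalled and near 0, and the cause was not tested. Over the fits without 1 library, Khdrbs1, Sam68 KO against wild type, day 0 ran from −0.07 (without Sam68 KO day 0 replicate 1) to 0.00 (without Sam68 KO day 0 replicate 3). Khdrbs2, Quaking KO against wild type, day 3 ran from −0.27 (without wild type day 3 replicate 2) to 0.02 (without wild type day 3 replicate 3). Khdrbs1, Quaking KO against wild type, day 10 ran from −0.23 (without wild type day 10 replicate 2) to 0.09 (without wild type day 10 replicate 1). Sf1, Quaking KO against wild type, day 10 was −0.03, 0.00 and 0.16, and Sf1, Sam68 KO against wild type, day 10 was −0.04, 0.00 and 0.15, without wild type day 10 replicates 2, 3 and 1, and without replicate 1 both were called. Qk, Sam68 KO against wild type, day 10 ran from −0.07 (without wild type day 10 replicate 2) to 0.02 (without wild type day 10 replicate 1), was 0.01 and 0.02 without Sam68 KO day 10 replicates 1 and 2, and was 0.02 with all 27 libraries in one fit. Sf1, wild type, day 3 against day 0 ran from −0.01 (without wild type day 0 replicate 2) to 0.03 (without wild type day 0 replicate 1), and was −0.01 with DESeq2 size factors, −0.06 on only protein-coding genes without shared sequence and −0.02 with all 27 libraries in one fit. Qk, wild type, day 3 against day 0 was 0.01 without wild type day 3 replicate 3.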

Other observations

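The tests of whole autosomes and of Quaking motifs were chosen before their results were seen.

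Other groups moved with differentiation in wild-type cells. By day 10, 18 of 22 imprinted genes rose and 1 fell (camera adjusted p = 6.17e-05; 0.0757 with an estimated correlation), all 14 genes of mesenchyme and the epithelial to mesenchymal transition rose (6.71e-06; 0.144 with an estimated correlation), and 13 of 15 endothelial genes rose with 1 falling (0.000333; 0.101 with an estimated correlation). In the Sam68-labelled line at day 10, 10 of 15 p53 targets rose and 2 fell (0.0183; 0.585 with an estimated correlation). In the day 10 interaction of Quaking KO, 9 of 14 Wnt targets were positive (6.38e-06; 0.21 with an estimated correlation). The Y-linked Eif2s3y was higher than wild type in the Sam68-labelled line, by 0.77 ± 0.04 at day 0, 0.52 ± 0.04 at day 3 and 1.15 ± 0.08 at day 10, while Kdm5d was lower, by log2FC −3.91 ± 0.46 at day 0 and at 0.00882 ± 0.00764 CPM against 0.291 ± 0.124 at day 10. Ddx3y was lower there too, at −0.76 ± 0.04 and −0.94 ± 0.04 at days 0 and 3, and did not pass at day 10 (−0.33 ± 0.14, adjusted p = 0.0675). Uty was lower at day 3 (−0.28 ± 0.05) and did not pass at day 0 (−0.07 ± 0.04) or day 10 (−0.04 ± 0.10).

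Genes of each chromosome were compared as a set, as a test of a gained or lost whole autosome behind the Quaking KO calls at day 0. The largest absolute median log2FC of an autosome over the 3 days was 0.21, for chromosome 6, which was the lowest autosome in all 6 comparisons of a knockout with wild type (−0.21, −0.09 and −0.10 in Quaking KO, −0.26, −0.12 and −0.11 in the Sam68-labelled line). That lies between the bounds set for a lost copy and for none. No autosome reached the bound for a gained or lost copy in Quaking KO at any day, which argues against such a change in all cells. A change in a share of the cells is left open. Both lines were set against the same wild-type libraries.

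Genes whose 3′ UTR holds the Quaking recognition motif were compared with genes of like UTR length without it, 2675 of 8344 genes at day 0 having it. Their median log2FC in Quaking KO differed by −0.017 at day 0, −0.002 at day 3 and −0.013 at day 10. The permutations tested another measure, the mean rank of the motif genes within UTR length bins. They gave permutation p = 0.0264 at day 0 (adjusted p = 0.0352), and adjusted p = 0.292 at day 3 and 0.005 at day 10. The reversed motif gave 0.001 at day 0 (permutation p = 0.012) and −0.02 at day 10 (permutation p = 1.00e-05, the smallest that 1e+05 permutations give). At day 0 this met the terms set for a role of the motif in the Quaking KO line (p under 0.05 and a smaller difference for the reversed motif). It also met the bound set against it (a difference within 0.05), so any such shift is small. The mean rank at day 0 was 0.492 for the motif and 0.492 for the reversed motif. On the measure that the permutations tested, the motif was therefore not set apart from its reversal. In the Sam68-labelled line the motif differences were −0.031, −0.042 and −0.04 at days 0, 3 and 10. Those of the reversed motif were smaller at each day (−0.02, −0.025 and 0.016). By permutation of the mean rank the motif had adjusted p = 0.0192, 0.005 and 0.0153, and the reversed motif 0.0153, 0.00573 and 0.707. Both thus passed at days 0 and 3, and only the Quaking motif at day 10. What causes those differences was not tested.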
